A study of Homo sapiens with 4 samples.

How the data were processed

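RNA was measured in 4 libraries of U937 cells, 2 without and 2 with 10 nM PMA for 72 h, 1 pair from each of 2 lots of cells. Per the labels' protocols, poly(A) RNA was enriched from total RNA and sequenced on an Ion Proton instrument. The submitters' processing notes name HISAT2 2.1.0 and StringTie 2.1.1 and give no roles for them. The genome build, the annotation, the counting program and the use of strand are not given in the sources used here, so antisense and overlapping genes and near-identical copies are uncertain, and no positions are printed.

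The main table holds estimated counts per gene deposited by the authors, not scaled between libraries, for 60662 genes and transcripts, of which 33746 are at 0 in all 4 libraries. The deposited values are whole numbers, so rounding changed none of them, although a count of 1 is more frequent (2617, 2248, 2357 and 2276 genes in untreated 1, untreated 2, PMA 1 and PMA 2) than 1 unit above it (874, 533, 781 and 604 genes). The second deposited table holds a signal per gene, which is the count times 1 factor per library. The same table holds the authors' log2 ratio of PMA to untreated and log2 mean level, and their p-value and q-value per gene. The test behind those p-values is not given in the sources used here. The largest q-value among the genes the authors called is 0.0500. Genes are named by the symbols in the deposited table. Of 798 genes in fixed lists, 797 were matched, 796 by symbol and 1 by another symbol of the same gene. Transcript length and GC content, both of the longest annotated transcript of a gene, and gene type came from GENCODE release 29. That release may not be the authors' annotation, and 58489 identifiers matched it.

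Depth was 35739833 to 54915928 counts per library, with 19080 to 23213 genes above 0. The 10 most abundant genes took 7.17% and 10.6% of counts in the untreated libraries and 11.3% and 12.2% in the PMA libraries. A count of 0 allows a level of up to 3 counts, which is 0.0475, 0.0695, 0.0921 and 0.0649 CPM in untreated 1, untreated 2, PMA 1 and PMA 2. Folds against a group at 0 are lower bounds against that floor in each library, which covers counting error only. A listed 0 can also be a failed estimate, since 1, 3, 0 and 1 genes in the same order were at 0 although they had at least 20 CPM in each of the other 3 libraries. Genes with 1 to 3 counts in a group are given as levels without a fold.

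Genes higher and lower with PMA were found with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr by group, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, on all 4 libraries without a block. The filter left 16451 genes. Levels are CPM of the TMM-scaled library size. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Gene lists with at least 5 tested members (36 of 44) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 36 lists, and again with a correlation estimated for each list, and with fry. With an estimated correlation, camera also uses the few residual degrees of freedom of the 4 libraries, which raises its p-values by itself. The lists hold pathways, complexes and markers of other cell types.

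The lot number in the titles pairs the libraries, and the deviations from the group means of libraries of the same lot correlated at 0.154 across genes. The fit with the lot as a block is an alternative. Nothing in the labels says that the lots were cultured apart, so the p-values measure the spread between these libraries, which may be technical. The group of each library, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule names the 10 genes with the highest and the 10 with the lowest fitted fold change past the threshold, changed the same way in both lots and at 10 CPM or more in the higher group. It adds up to 3 members of each list with the smallest p, 1 member past the threshold in the opposite direction, a set of genes fixed by name, and the 10 most abundant genes of each group. Not every gene the rule names is printed, and the results of some are not reported here.

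Alternatives were other scaling factors (RLE and upper quartile), no filter and a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the lot as a block, a test against a fold of 1.5, an adjusted p under 0.01, leaving out each library, library sizes without the 20 most abundant and the mitochondrial genes, and summing of entries with 1 symbol. Offsets for length and GC content, the same with the block, and protein-coding genes only were added after the data had been seen. Upper-quartile factors moved the median log2 fold change of all genes to −0.17, against 0.00 with TMM.

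The tests were tested on simulated data with the spread of these libraries. The changed genes, 50 per fold size in 15507 tested, were at 10 CPM or more on average, so genes at lower levels are not covered. Among them, edgeR recovered 22% at 4-fold, 92% at 16-fold, 98% at 64-fold and 100% at 256-fold. It called 11 unchanged genes. In a second simulation with a dispersion of 0.05, against 0.391 estimated here, 100% were recovered at each size. Camera on 35 simulated lists found the 1 list that had been lowered and 0 others. The simulated genes were drawn independently, while the estimated correlation within the lists of these data had a median of 0.145. That simulation therefore cannot show how often camera calls lists of correlated genes.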

Results

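Gene expression was measured by RNA sequencing in U937, an established human myeloid cell line that came from a histiocytic lymphoma. Cells were cultured with or without 10 nM phorbol 12-myristate 13-acetate (PMA), a phorbol ester that activates protein kinase C, for 72 h. The labels give the purpose of the treatment as differentiation into macrophage-like cells. There were 2 libraries without PMA and 2 with PMA, 1 of each from 2 lots of cells. Total counts were 54915928 and 41308603 in the untreated libraries of lots 1 and 2, and 35739833 and 50822971 in the PMA libraries. Levels are normalised CPM, counts scaled to a common library size, given as mean ± SD with n = 2 libraries per group. Log2 fold changes compare PMA with untreated cells and carry their standard error.

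With PMA, 12 of 19 monocyte and macrophage surface markers and 13 of 27 interferon-stimulated genes rose, while 16 of 30 mitosis and G2/M genes and 10 of 32 cytosolic ribosomal protein genes fell. Each of these 4 lists was called by camera, and each call was lost with an estimated correlation (adjusted p = 0.253, 0.224, 0.332 and 0.224 with an estimated correlation). The same happened to lists whose estimated correlation was below the preset 0.01, so the loss does not mark correlated genes alone. The integrin subunit ITGAX rose from 12.5 ± 0.0784 to 2307 ± 563 CPM, and the CDK inhibitor CDKN1A from 6.45 ± 1.00 to 1176 ± 34.9 CPM. The transcription factor MYC fell from 347 ± 24.5 to 43.7 ± 4.85 CPM, and the replication helicase subunit MCM2 from 370 ± 50.7 to 26.1 ± 6.18 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 705 genes were higher and 332 lower with PMA among 16451 tested. All 1037 changed the same way in both lots, against 74.5% of all tested genes. The test favours such genes with 2 libraries per group, so this is no separate support for the calls. Of the 1037 genes, 68.0% were higher, while DESeq2 called 2193 higher and 1712 lower. The smallest adjusted p was 0.0148, and 4445 genes had an unadjusted p under 0.05. Among the called genes, 159 were at 0 in both untreated libraries and 40 were at 0 in both PMA libraries. The other called genes had a median log2 fold change of 3.36 if higher and −2.96 if lower. Leaving out untreated replicate 1 gave 1830 higher and 1085 lower genes, leaving out PMA replicate 1 gave 467 and 277, and leaving out PMA replicate 2 gave 424 and 79. Without PMA replicates 1 and 2 in turn, most of the 332 lower genes were no longer called. The spread between replicates was large, with a coefficient of variation of 0.626 by edgeR. In simulated genes at 10 CPM or more, with the spread estimated for each gene, 22% of 4-fold changes passed the test.

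The 10 genes ranked highest by the fitted fold change were all at 0 in both untreated libraries, where the fitted value rests on a prior count. Their order is therefore not established, nor is their place above SPP1 and ITGB7, which had a few untreated counts. A2M, the protease inhibitor alpha-2-macroglobulin, reached 3549 ± 1591 CPM with PMA (ENSG00000175899.14, at least 60653-fold higher, adjusted p = 0.0148). The gelatinase MMP9 reached 1760 ± 221 CPM (at least 30081-fold) and the matrilysin MMP7 837 ± 37.8 CPM (at least 14304-fold). TDO2, a tryptophan-degrading enzyme, reached 748 and 272 CPM in lots 1 and 2, the G-protein regulator RGS1 496 ± 137 CPM and the chemokine CCL1 347 ± 93.5 CPM. VWF, the von Willebrand factor of endothelial cells and platelets, reached 153 and 496 CPM, and INHBA, the activin A subunit, 301 ± 86.1 CPM. The lipid receptor TREM2 reached 279 ± 11.3 CPM (at least 4763-fold) and the transcription factor EGR2 263 ± 8.68 CPM (at least 4493-fold). All 10 had adjusted p-values from 0.0148 to 0.0236. These folds are lower bounds, set against a floor of 3 counts in each untreated library.

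At the other end, 4 of the 10 genes ranked lowest by the fitted fold change were at 0 in both PMA libraries. MLC1 fell from 60.9 ± 26.9 CPM (at least 776-fold lower, adjusted p = 0.0221), the myeloid progenitor gene MS4A3 from 38.6 ± 2.92 CPM (at least 492-fold), IGLL1 from 33.1 ± 5.39 CPM (at least 422-fold) and SPNS3 from 12.3 ± 6.15 CPM (at least 157-fold). The azurophil granule proteases also fell, PRTN3 (proteinase 3) from 149 ± 73.6 to 0.420 ± 0.318 CPM (−8.50 ± 0.88, adjusted p = 0.0224) and ELANE (neutrophil elastase) from 697 ± 394 to 8.55 ± 0.635 CPM (−6.35 ± 0.59, adjusted p = 0.0203). The replication licensing factor CDT1 fell from 179 ± 22.7 to 3.60 ± 1.09 CPM (−5.64 ± 0.44, adjusted p = 0.0163) and its ubiquitin ligase adaptor DTL also fell (−5.92 ± 0.96, adjusted p = 0.0377). The channel gene KCNN2 went from 19.1 ± 3.03 CPM to 3 counts in 1 PMA library and 0 in the other (adjusted p = 0.0311). The centromere gene CENPM had a log2 fold change of −8.87 ± 1.53 (adjusted p = 0.0414). With the lot as a block its adjusted p was 0.0581, within a range of 0.00197 to 0.0662 over the alternatives. With the block and length and GC offsets together it was 0.0520 for SPNS3 and 0.0511 for KCNN2, against 2.24e-10 and 2.50e-15 with DESeq2.

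**Figure D1:**
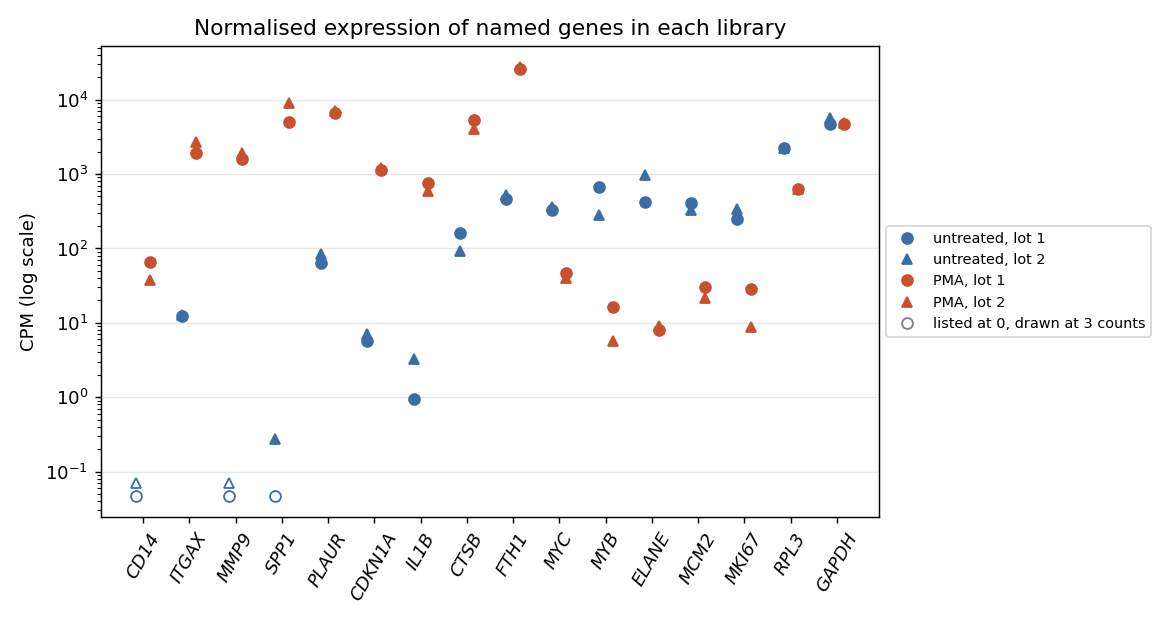
CPM on a log axis in each library for 16 genes named in the text, with circles for lot 1, triangles for lot 2, blue for untreated and red-orange for PMA, and open symbols at the level of 3 counts for genes listed at 0. ITGAX lay at 12.5 and 12.6 CPM without PMA and at 1908 and 2705 CPM with PMA, while GAPDH lay between 4705 and 5597 CPM in all 4 libraries.

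Of 19 surface markers of mature monocytes and macrophages tested, 12 rose and 0 fell, or 16 and 0 adjusted over the list alone, and the list ranked above the other genes (camera adjusted p = 3.25e-11, adjusted p = 0.253 with an estimated correlation). ITGAX had a log2 fold change of 7.53 ± 0.41 (adjusted p = 0.0148). The lipopolysaccharide co-receptor CD14, at 0 without PMA, reached 51.4 ± 19.1 CPM (at least 878-fold higher, adjusted p = 0.0203), and the haemoglobin scavenger receptor CD163 was at 105 and 24.5 CPM in lots 1 and 2 (at least 1107-fold, or 419-fold by lot 2 alone, adjusted p = 0.0310). The call of CD163 was lost with limma-voom (adjusted p = 0.0552, against 1.32e-15 with DESeq2). The lectin CD209 went from 0.0390 ± 0.0104 to 201 ± 81.9 CPM (adjusted p = 0.0148), ITGAM changed by 5.76 ± 0.55 and the lysosomal glycoprotein CD68 by 3.21 ± 0.43 (adjusted p = 0.0280). CSF1R, the receptor of macrophage colony-stimulating factor, was at 0 and 1.74 CPM without PMA and at 667 and 332 CPM with it. It did not pass the test (adjusted p = 0.0657, and 0.0117 to 0.0996 over 17 alternatives, in 7 of which it did not pass). Of 14 lipid-handling macrophage genes, 6 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 7.50e-08, adjusted p = 0.224 with an estimated correlation). Among them, the chitinase-like CHI3L1 rose by 5.58 ± 0.52, the galectin LGALS3 by 3.30 ± 0.34, and the chitinase CHIT1 from 0.111 ± 0.157 to 387 ± 10.9 CPM. Osteopontin (SPP1) went from 0.139 ± 0.197 to 7073 ± 2799 CPM (adjusted p = 0.0229). APOE stayed at 1.97 CPM or below in every library (adjusted p = 0.629).

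Some genes of immature myeloid cells fell. In the azurophil granule list, 4 of 13 tested genes fell and 0 rose, or 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00485, adjusted p = 0.259 with an estimated correlation). Without untreated replicate 2 the list's adjusted p was 0.0833, and 0.00196 was the lowest over the alternatives. Myeloperoxidase (MPO) was listed at 0 in all 4 libraries. Of 8 haematopoietic progenitor genes, 3 fell and 0 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.000225, adjusted p = 0.332 with an estimated correlation). The progenitor transcription factor MYB fell from 474 ± 272 to 10.9 ± 7.38 CPM (−5.45 ± 0.80, adjusted p = 0.0323), BCL11A by 3.88 ± 0.61 (adjusted p = 0.0356) and the nucleolar protein gene NPM1 by 1.58 ± 0.28 (adjusted p = 0.0454). With the lot as a block the adjusted p was 0.0539 for BCL11A and 0.0627 for NPM1. Without PMA replicates 1 and 2 in turn it was 0.0907 and 0.0580 for BCL11A and 0.253 and 0.233 for NPM1, and DESeq2 gave the lowest values of the alternatives (4.19e-09 and 0.000129). Of 18 myeloid transcription factors, 4 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0484, adjusted p = 0.300 with an estimated correlation). The HLH inhibitor ID2 rose by 3.01 ± 0.35, while the repressor GFI1 fell by 3.07 ± 0.41 (adjusted p = 0.0281). Without PMA replicate 2 the adjusted p was 0.0615 for ID2 and 0.0582 for GFI1, and without PMA replicate 1 it was 0.0762 for GFI1, against 3.60e-12 and 1.15e-09 with DESeq2. With the block and length and GC offsets together it was 0.0559 for GFI1 and 0.0808 for NPM1, and for NPM1 it was 0.0554 without a filter and 0.0706 against a fold of 1.5. The list's adjusted p was 0.0515 with RLE factors, 0.152 without untreated replicate 1 and 0.118 without PMA replicate 2, and 0.0104 at its lowest over the alternatives.

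Immediate early genes respond to growth factor and protein kinase C signalling. Of 23 such genes, 13 rose and 0 fell, or 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.52e-08, adjusted p = 0.300 with an estimated correlation). EGR3, at 0 without PMA, was at 55.9 and 121 CPM in lots 1 and 2 with it (at least 1514-fold higher, or 956-fold by lot 1 alone, adjusted p = 0.0221), and the MAP kinase phosphatase DUSP4 rose by 3.90 ± 0.36 (adjusted p = 0.0202). The 8 tested protein kinase C isoforms had no call over all genes, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.680, adjusted p = 0.830 with an estimated correlation). PRKCB was at 287 ± 165 and 308 ± 141 CPM (0.10 ± 0.56, and −0.040 with upper-quartile factors), PRKCD at 198 ± 73.9 and 301 ± 19.0 CPM (adjusted p = 0.378), and PRKCQ at 7.13 ± 0.279 and 0.959 ± 0.163 CPM (adjusted p = 0.0628, and 0.000155 to 0.302 over 17 alternatives, in 14 of which it did not pass). PRKCA had 3 counts in 1 untreated library and 0 in the others and was not tested.

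Of 30 DNA replication and G1/S genes, 15 fell and 0 rose, or 27 and 0 adjusted over the list alone, and 29 were lower in both lots (camera adjusted p = 4.39e-14, adjusted p = 0.224 with an estimated correlation). MCM2 fell by 3.82 ± 0.37 (adjusted p = 0.0211) and MCM3 by 3.13 ± 0.30 (adjusted p = 0.0211). Of 30 mitosis and G2/M genes, 16 fell and 0 rose, or 25 and 0 adjusted over the list alone, and all 30 were at least 2-fold lower in both lots (camera adjusted p = 4.39e-14, adjusted p = 0.332 with an estimated correlation). The inhibitor of apoptosis and mitotic gene BIRC5 fell by 5.36 ± 0.57 (adjusted p = 0.0224), the spindle genes HMMR by 4.41 ± 0.45 and PRC1 by 3.89 ± 0.37, and the proliferation marker MKI67 from 292 ± 65.1 to 18.8 ± 14.3 CPM (−3.96 ± 0.69, adjusted p = 0.0426). With the lot as a block the adjusted p of MKI67 was 0.0546, and against a fold of 1.5 it was 0.0505. Without PMA replicate 2 it was 0.0671 for MKI67, 0.0694 for MCM3, 0.0611 for PRC1 and 0.0645 for HMMR, without PMA replicate 1 it was 0.0516 for MCM3, and without untreated replicate 2 it was 0.0563 for MKI67. DESeq2 gave the lowest values of the alternatives, at most 6.12e-08 for these genes, and the highest was 0.0734 for MKI67, with the block and length and GC offsets together. Among 18 CDK inhibitors and p53 targets, 4 rose and 1 fell, or 5 and 2 adjusted over the list alone. The list's median log2 fold change was −0.12 while its test pointed up (camera adjusted p = 0.689, adjusted p = 0.886 with an estimated correlation). CDKN1A (p21) rose by 7.51 ± 0.38 (adjusted p = 0.0148) and the antiproliferative BTG2 by 4.72 ± 0.49, while the CDK4 and CDK6 inhibitor CDKN2C fell by 3.36 ± 0.43 (adjusted p = 0.0272). The adjusted p of CDKN2C was 0.0788 and 0.138 without PMA replicates 1 and 2 in turn, and 1.05e-11 with DESeq2.

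Of 28 ribosome biogenesis genes and MYC targets, 7 fell and 0 rose, or 21 and 0 adjusted over the list alone (camera adjusted p = 1.74e-08, adjusted p = 0.300 with an estimated correlation). MYC fell by 2.99 ± 0.32 (adjusted p = 0.0224), the rRNA methyltransferase FBL by 3.32 ± 0.48 and the pre-rRNA nuclease NOB1 by 2.14 ± 0.31. Of 32 cytosolic ribosomal protein genes, 10 fell and 0 rose, or 30 and 0 adjusted over the list alone, and all 32 were lower in both lots (camera adjusted p = 3.76e-10, adjusted p = 0.224 with an estimated correlation). Their median log2 fold change was −1.41. RPL3 fell from 2239 ± 12.2 to 631 ± 0.179 CPM (−1.83 ± 0.27, adjusted p = 0.0320), RPS2 from 2491 ± 693 to 520 ± 19.3 CPM, and RPS3 by 1.67 ± 0.30 (adjusted p = 0.0448, and 0.0625 with the lot as a block). These genes have many processed pseudogenes with which reads can be shared, so single values are uncertain. Without PMA replicates 1 and 2 in turn, the adjusted p was 0.0524 and 0.0896 for MYC, 0.0615 and 0.0950 for FBL, 0.196 and 0.225 for NOB1, 0.102 and 0.114 for RPL3, 0.0654 and 0.0678 for RPS2, and 0.130 and 0.246 for RPS3. For RPS3 it was 0.0552 without untreated replicate 2, 0.0507 with RLE factors and 0.0677 against a fold of 1.5. DESeq2 gave the lowest values of the alternatives, at most 0.000146 for these genes. With the block and length and GC offsets together it was 0.0528 for FBL, 0.0561 for NOB1, 0.0580 for RPL3, 0.0502 for RPS2 and 0.0837 for RPS3.

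Among the energy metabolism genes of 3 lists, 1 passed the test over all genes. None of 30 nuclear oxidative phosphorylation genes passed the test over all genes or adjusted over the list alone, although the list ranked below the other genes (camera adjusted p = 0.0365, adjusted p = 0.593 with an estimated correlation). That call was lost with the lot as a block (adjusted p = 0.0505), after removal of length and GC trends (0.150, and 0.171 with the block), without untreated replicate 2 (0.246) and without PMA replicate 2 (0.162), and the lowest value over the alternatives was 0.00250. NDUFV1, the member with the smallest p, was at 198 ± 51.0 and 57.8 ± 14.7 CPM (adjusted p = 0.0610, and 0.000942 to 0.406 over 17 alternatives, in 11 of which it did not pass). The 13 mitochondrially encoded mRNAs had no call over all genes or the list alone (camera adjusted p = 0.639), and MT-ND1 was at 976 and 5121 CPM without PMA and at 604 and 1853 CPM with PMA. The share of counts from the mitochondrial genome followed the lots, at 3.66% and 2.81% in lot 1 and 8.58% and 5.99% in lot 2 (untreated and PMA). Without untreated replicate 1 the adjusted p of this list was 0.0467, against 0.782 at its highest over the alternatives. Of 20 glycolysis genes, 1 rose and 0 fell over all genes and over the list alone (camera adjusted p = 0.607). This was the glucose transporter SLC2A3, which rose by 3.62 ± 0.45 (adjusted p = 0.0264).

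Lists of inflammatory signalling genes held genes that rose and none that fell over all genes tested. Of 17 cytokine genes, 6 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 6.20e-05, adjusted p = 0.224 with an estimated correlation). Interleukin 1 beta (IL1B) rose from 2.12 ± 1.66 to 675 ± 116 CPM (8.32 ± 0.84, adjusted p = 0.0222), the growth factor HBEGF by 4.96 ± 0.43, and LIF from 0 to 20.3 ± 1.57 CPM (at least 348-fold). TNF was at 1.26 ± 1.72 and 5.45 ± 3.64 CPM (adjusted p = 0.488). Of 16 chemokines, 10 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 4.81e-11, adjusted p = 0.224 with an estimated correlation). CCL24 and CCL4 were both at 0 without PMA. With PMA, CCL24 was at 65.8 and 85.6 CPM (at least 1294-fold higher) and CCL4 at 37.0 ± 14.8 CPM (at least 632-fold), and CXCL8 (interleukin 8) rose by 7.52 ± 1.21 (adjusted p = 0.0373). CCL2 was at 2.14 and 29.6 CPM without PMA and 706 and 386 CPM with it, and did not pass (adjusted p = 0.0853, and 5.69e-06 to 0.114 over 17 alternatives, in 12 of which it did not pass). Of 9 chemoattractant receptors, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 8.14e-05, adjusted p = 0.300 with an estimated correlation). They included CCR1 (5.63 ± 0.40), the chemerin receptor CMKLR1 (at least 1981-fold) and the formyl peptide receptor FPR1 (at least 482-fold). Of 22 NF-kB pathway genes, 7 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 1.08e-05, adjusted p = 0.300 with an estimated correlation). TRAF1 rose by 7.01 ± 0.46, CD83 by 4.47 ± 0.67 and RELB by 2.75 ± 0.39 (adjusted p = 0.0310). The adjusted p of RELB was 0.0829 and 0.139 without PMA replicates 1 and 2 in turn, and 1.91e-09 with DESeq2. With the block and length and GC offsets together it was 0.0644 for CXCL8, 0.0534 for CD83 and 0.0507 for CLEC5A, against at most 5.57e-11 with DESeq2. Of 16 pattern recognition receptors, 7 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 5.20e-07, adjusted p = 0.224 with an estimated correlation). The beta-glucan receptor CLEC7A (at least 300.4-fold), CLEC5A (4.03 ± 0.45) and TLR2 (4.68 ± 0.56, adjusted p = 0.0253) rose, while TLR4 was at 27.3 ± 5.69 and 79.8 ± 31.5 CPM (adjusted p = 0.0993, and 0.0104 with DESeq2 to 0.620 over 17 alternatives, in 16 of which it did not pass).

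Of 27 interferon-stimulated genes tested, 13 rose and 0 fell, or 26 and 0 adjusted over the list alone, and 26 were at least 2-fold higher in both lots (camera adjusted p = 1.61e-12, adjusted p = 0.224 with an estimated correlation). The antiviral enzyme OAS3 rose from 16.7 ± 3.71 to 696 ± 125 CPM (5.38 ± 0.40, adjusted p = 0.0158) and the RNA sensor DDX58 by 4.33 ± 0.52 (adjusted p = 0.0253). Of 21 antiviral restriction factors and nucleic acid sensors, 1 rose and 0 fell, or 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0484, adjusted p = 0.444 with an estimated correlation). The gene that rose was the dNTP hydrolase SAMHD1 (4.09 ± 0.45, adjusted p = 0.0236). The list's adjusted p was 0.0507 with the lot as a block, 0.329 without untreated replicate 1 and 0.0854 without PMA replicate 2, and 0.0114 at its lowest over the alternatives. Of 13 genes of MHC class I presentation, 1 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.495 with an estimated correlation). B2M, the class I light chain, rose from 486 ± 70.0 to 2797 ± 451 CPM (adjusted p = 0.0257). Without untreated replicate 1 the list's adjusted p was 0.172, against 0.00133 at its lowest. The 5 tested MHC class II genes had no call over all genes, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.685). The class II transactivator CIITA was at 16.8 ± 7.66 and 0.153 ± 0.217 CPM (adjusted p = 0.0717). Its call depended on the setting, with an adjusted p of 4.07e-07 to 0.0847 over 17 alternatives, in 11 of which it did not pass.

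From the adhesion and matrix lists, ITGB2 and PLAUR were among the 10 most abundant genes with PMA. Of 21 integrin and adhesion genes, 10 rose and 0 fell, or 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.83e-07, adjusted p = 0.224 with an estimated correlation). The shared beta subunit of the leukocyte integrins, ITGB2, rose from 930 ± 4.41 to 11219 ± 1086 CPM (3.59 ± 0.28), PECAM1 by 4.97 ± 0.38, and ITGB7 from 0.0511 ± 0.0396 to 550 ± 209 CPM (adjusted p = 0.0148). Of 20 genes for extracellular matrix, proteases and inhibitors, 12 rose and 0 fell, or 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.67e-10, adjusted p = 0.224 with an estimated correlation). The membrane protease MMP14 rose by 9.08 ± 0.40 (adjusted p = 0.0148), and the urokinase receptor PLAUR from 73.0 ± 14.4 to 6858 ± 274 CPM (6.55 ± 0.36). Of 29 lysosomal genes, 5 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 7.50e-08, adjusted p = 0.296 with an estimated correlation). Cathepsin B (CTSB) rose from 126 ± 46.2 to 4677 ± 957 CPM, cathepsin S (CTSS) by 3.24 ± 0.36 and the proton pump subunit ATP6V0D2 by 7.58 ± 0.84. Of 7 NADPH oxidase genes, 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00959, adjusted p = 0.366 with an estimated correlation). The catalytic subunit CYBB rose by 5.95 ± 0.65 and the GTPase RAC2 by 1.99 ± 0.37 (adjusted p = 0.0474). The adjusted p of RAC2 was 0.105 and 0.159 without PMA replicates 1 and 2 in turn, 0.0528 with RLE factors, 0.0663 with upper-quartile factors, 0.0516 with library sizes without the most abundant and mitochondrial genes and 0.0660 against a fold of 1.5, and 6.53e-05 with DESeq2. With the block and length and GC offsets together it was 0.0561 for CTSS and 0.0554 for CYBB, against 1.67e-13 and 1.47e-21 with DESeq2. The list's adjusted p was 0.0862 without untreated replicate 1 and 0.0676 without PMA replicate 1, and 0.00406 at its lowest. Of 10 complement genes, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.000195, adjusted p = 0.224 with an estimated correlation). C3 rose by 8.20 ± 0.50, properdin (CFP) by 6.20 ± 0.57, and C1QC from 0 to 26.7 and 8.87 CPM in lots 1 and 2 (at least 304-fold, or 152-fold by lot 2 alone).

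Iron, metal and sterol genes changed in part. FTH1, the ferritin heavy chain, rose from 487 ± 41.1 to 26541 ± 1002 CPM (5.77 ± 0.29, adjusted p = 0.0148), while the light chain FTL was at 13349 ± 2079 and 32346 ± 8279 CPM, higher in both lots (log2 differences of 1.69 and 0.84), and did not pass (adjusted p = 0.0712). Over 17 alternatives the adjusted p of FTL was 0.0105 to 0.1996, and it did not pass in 14 of them. FTH1 has processed pseudogenes with which its reads can be shared. Of 11 iron and haem genes, 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0477, adjusted p = 0.428 with an estimated correlation). The divalent metal transporter SLC11A1 rose by 5.20 ± 0.53 and the transferrin receptor TFRC by 2.45 ± 0.37 (adjusted p = 0.0348). The list's adjusted p was 0.0586 with the lot as a block, 0.0714 with that and length and GC trends removed, and 0.0667, 0.0640 and 0.146 without untreated replicate 1, PMA replicate 1 and untreated replicate 2, against 0.00871 at its lowest. For TFRC it was 0.142, 0.0539 and 0.0517 without PMA replicate 1, untreated replicate 2 and PMA replicate 2, against 3.83e-07 with DESeq2, and 0.0713 with the block and length and GC offsets together. Of 6 metallothioneins, 2 fell and 0 rose, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.00153, adjusted p = 0.329 with an estimated correlation). MT1G fell by 4.01 ± 0.56 (adjusted p = 0.0303) and MT1E by 3.08 ± 0.58 (adjusted p = 0.0485), and these paralogs can share reads. Without PMA replicate 2 the adjusted p was 0.0896 for MT1G and 0.184 for MT1E, and without PMA replicate 1 it was 0.0852 for MT1E, against 6.30e-11 and 4.21e-06 with DESeq2. For MT1E it was 0.0590 with length and GC offsets, 0.0507 with these and the block, and 0.0594 against a fold of 1.5. Of 22 cholesterol synthesis genes, 1 rose and 0 fell over all genes and over the list alone (camera adjusted p = 0.688). It was the squalene epoxidase SQLE (2.64 ± 0.35, adjusted p = 0.0281), with an adjusted p of 0.0703 without PMA replicate 2 and 4.21e-09 with DESeq2. Without PMA replicate 1 the list's adjusted p was 0.0268, against 0.827 at its highest. Of 11 liver X receptor targets, 2 rose and 0 fell, or 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0566, adjusted p = 0.317 with an estimated correlation). The cholesterol exporter ABCA1, at 0 without PMA, was at 95.5 and 15.7 CPM with it (at least 951-fold higher, or 269-fold by lot 2 alone, adjusted p = 0.0385, and 0.0798 with limma-voom against 3.05e-14 with DESeq2), and the nuclear receptor RXRA rose by 1.79 ± 0.30 (adjusted p = 0.0393). The adjusted p of RXRA was 0.0535 with the lot as a block, 0.0552 with upper-quartile factors and 0.0572 against a fold of 1.5, and without PMA replicates 1 and 2 in turn it was 0.217 and 0.232, against 9.67e-06 with DESeq2, and with the block and length and GC offsets together 0.0797. The list's adjusted p was 0.0129 without PMA replicate 1, 0.0179 without a filter and 0.192 at its highest.

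Few genes of the stress and histone lists passed the test. Of 19 genes of the unfolded protein and integrated stress responses, 2 fell and 0 rose, or 2 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.904). Both genes that fell encode serine synthesis enzymes, PHGDH from 401 ± 79.1 to 10.4 ± 4.10 CPM (−5.26 ± 0.48, adjusted p = 0.0202) and PSAT1 by 3.78 ± 0.66 (adjusted p = 0.0426). The adjusted p of PSAT1 was 0.0686 with the lot as a block, 0.0508 against a fold of 1.5 and 0.0858 and 0.0518 without PMA replicates 1 and 2 in turn, and 0.0754 with the block and length and GC offsets together, against 1.08e-07 with DESeq2. None of 12 heat shock genes (camera adjusted p = 0.607) or 16 replication-dependent histone genes (camera adjusted p = 0.424) passed over all genes or over the list alone. In these poly(A)-enriched libraries the 29 histone genes summed to 115 CPM without PMA and 136 CPM with it, and 13 were not tested. The result therefore does not show that histone expression was unchanged. The chaperonin HSPD1 was at 620 ± 224 and 176 ± 41.7 CPM (adjusted p = 0.0636) and H2BC17 at 5.00 ± 1.45 and 0.218 ± 0.125 CPM (adjusted p = 0.0548). Over the alternatives the adjusted p was 0.00138 to 0.325 for HSPD1, which did not pass in 12 of 17, and 1.90e-05 to 0.208 for H2BC17, which did not pass in 13 of 16. Without untreated replicate 2 the heat shock list had an adjusted p of 0.0205, and without untreated replicate 1 the histone list had 0.0139, against highest values of 0.790 and 0.940.

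**Figure D2:**
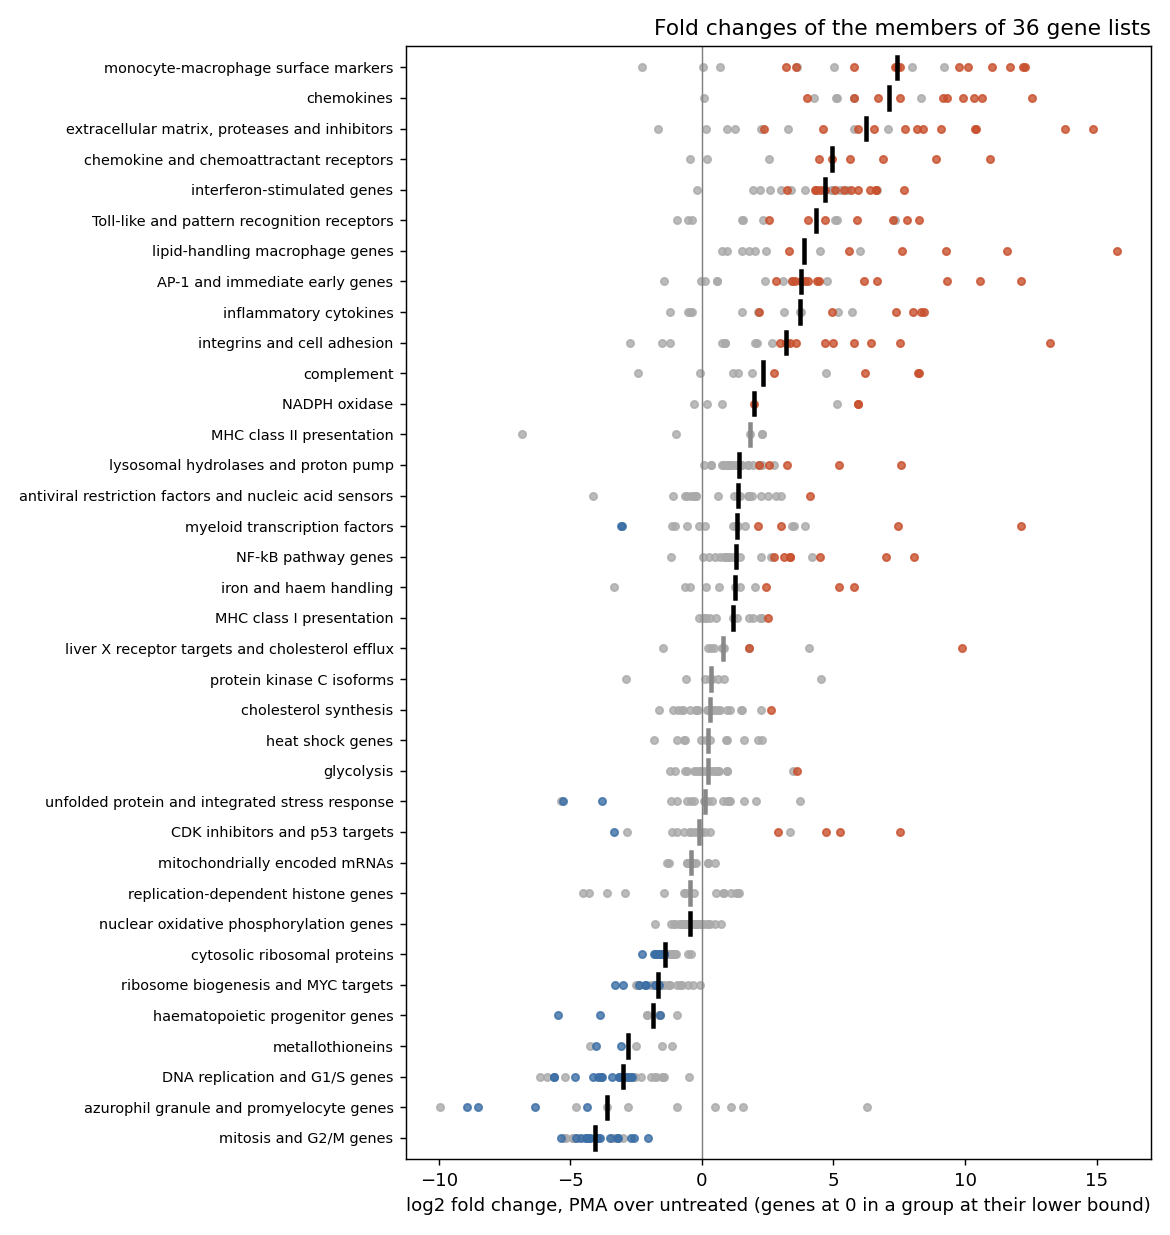
Log2 fold change (PMA over untreated) of each tested member of 36 gene lists, with genes at 0 in a group placed at their bound, coloured points for genes past the test, and ticks for the list medians (black where camera's adjusted p was under 0.05). The tick for mitosis and G2/M genes lies at −4.06 and that for surface markers at 7.40.

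Lists with few tested genes served as markers of other cell types. Platelet VWF rose, and it was the 1 gene called among 3 tested megakaryocyte and platelet genes (3 adjusted over the list alone). All 10 genes of that list, tested or not, summed to 3.24 CPM without PMA and 1500 CPM with it, of which PPBP, which did not pass (adjusted p = 0.0956), made up 2.57 and 1174 CPM. Of 3 dendritic cell genes, CLEC10A (at least 223-fold higher, or 146-fold by lot 1 alone, adjusted p = 0.0272) and XCR1 (at least 76.4-fold, adjusted p = 0.0361) rose, with 2 rising over the list alone, at 13.0 ± 6.37 and 4.47 ± 1.33 CPM. The adjusted p of XCR1 was 0.0656 with the lot as a block, 0.0761 with that and length and GC offsets, and 0.0675 without PMA replicate 2, against 1.03e-07 with DESeq2. The other marker lists had no call over all genes by edgeR on all 4 libraries, with 3 tested genes each for specific granules, T and NK cells, B cells and mast cells, 2 for erythroid cells and 1 for epithelial cells and fibroblasts. Among the genes with the smallest p in these were MMP8 (1.61 ± 1.95 and 82.1 ± 91.7 CPM, adjusted p = 0.107), GNLY (0 and 2.58 ± 1.92 CPM, adjusted p = 0.0583), HDC (0.0633 ± 0.0895 and 12.0 ± 7.72 CPM, adjusted p = 0.0554) and KLF1 (5.54 ± 3.67 and 0.460 ± 0.651 CPM, adjusted p = 0.317). Some alternatives called them, HDC failing in 9 of 17 (adjusted p from 1.59e-09 to 0.102), GNLY in 12 of 16 (3.17e-05 to 0.293), MMP8 in 15 of 17 (2.57e-05 to 0.2504) and KLF1 in 15 of 16 (0.0338 to 0.515). Adjusted over the list alone, 3 mast cell genes rose, 1 T and NK cell gene rose and 1 fell, and 0 passed in the specific granule, B cell, erythroid and epithelial lists. The 3 mast cell genes were at least 2-fold higher in both lots. Whole lists summed to 300 CPM without and 112 CPM with PMA for T and NK cells, and to 338 and 831 CPM for mast cells. The sums were 115 and 174 CPM for specific granules, 22.6 and 12.4 for B cells, 19.7 and 8.76 for erythroid cells, and 0.483 and 0.593 for epithelial cells and fibroblasts. The gene commonly used for scaling, GAPDH, was at 5183 ± 586 and 4807 ± 145 CPM (adjusted p = 0.833), and ACTB at 7764 ± 5580 and 6420 ± 1148 CPM (adjusted p = 0.807).

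In all, camera placed 18 of 36 lists above the other genes and 8 below them. With a correlation between genes estimated for each list, 0 of them passed, with 6 lists at an unadjusted p under 0.05. Calls were also lost where the estimate was below the preset 0.01. Camera's unadjusted p went from 2.25e-08 to 0.0271 for lipid-handling genes (estimate −0.0052) and from 6.69e-12 to 0.0184 for chemokines (0.0016). In such lists the loss cannot be put down to correlation between genes. With an estimated correlation, camera also uses the few residual degrees of freedom of 4 libraries, which raises its p-values by itself. In the other lists the part of correlation was not separated from this. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 22 lists, the smallest adjusted p being 0.00268. Of the 26 lists called by camera, 19 passed in every other setting of camera tried, with adjusted p-values of 0.0310 or lower. Among these 19, fry did not call the metallothioneins (fry adjusted p = 0.0545).

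The change with PMA was compared between the lots. Across the tested genes, the log2 difference between the PMA and untreated library had a Pearson correlation of 0.683 and a Spearman correlation of 0.642 between lot 1 and lot 2, where genes are not independent replicates. In both lots, 2760 genes were at least 2-fold higher and 2337 at least 2-fold lower, and 539 differed by at least 2-fold in opposite ways. Libraries of 1 group correlated at 0.895 (untreated) and 0.923 (PMA), and libraries of 1 lot but different groups at 0.796 and 0.730. A fit with lot and treatment found 0 genes with a difference between lots by edgeR, against 108 by DESeq2. By edgeR, 925 of 16451 tested genes had an unadjusted p under 0.05, near the number expected without any difference. The difference between the lots went with transcript length and GC content. Across 10629 genes at 5 CPM or more on average, the untreated lot 2 minus lot 1 difference had a Spearman correlation of −0.418 with length. With GC content it was 0.485. Across the same genes, the PMA difference had a Spearman correlation with length of 0.120 in lot 1 and 0.282 in lot 2.

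**Figure D3:**
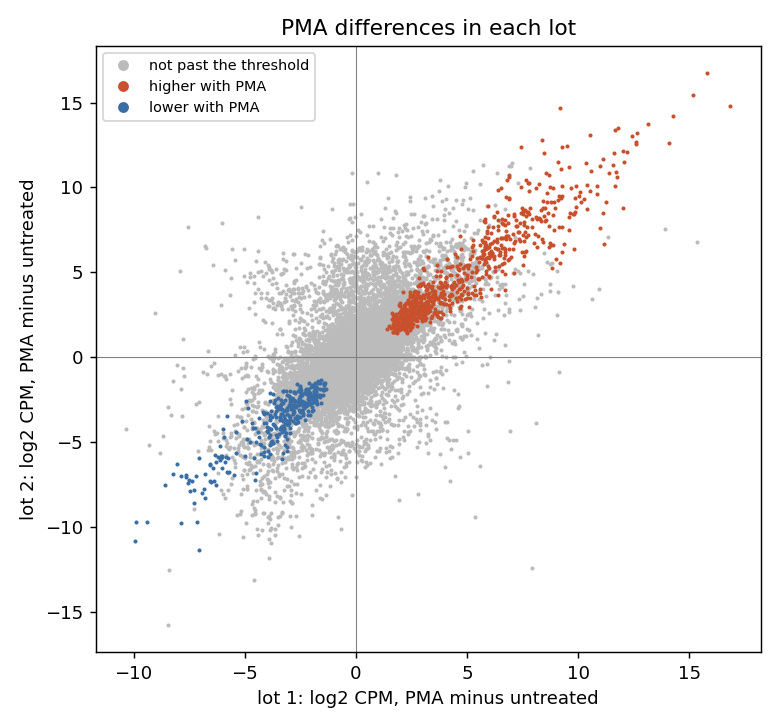
Log2 difference in CPM between PMA and untreated libraries in lot 1 (x axis) and lot 2 (y axis), 1 point per tested gene, with the 705 higher and 332 lower genes coloured. The Pearson correlation across genes was 0.683. Every coloured point lies on the same side of 0 in both lots, which the selection of these genes favours, against 74.5% of all tested genes.

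**Figure D4:**
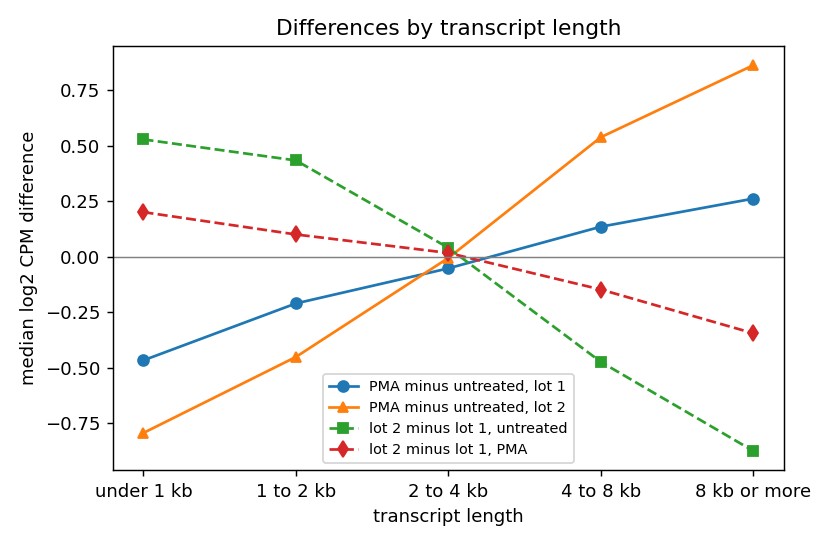
Median log2 difference of genes at 5 CPM or more on average, in 5 classes of transcript length. Lines show PMA against untreated in each lot and lot 2 against lot 1 in each group. The PMA difference went from −0.47 to 0.26 in lot 1 and from −0.79 to 0.86 in lot 2, and the untreated difference between lots from 0.53 to −0.87.

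The authors' deposited table holds their own comparison of the same libraries. There are 1347 called genes in the authors' deposited table, 897 higher and 450 lower with PMA. Of these, 604 of the higher and 235 of the lower genes were also called by edgeR, which started from the same counts. There were 0 opposite calls between edgeR and the authors' deposited table, and 101 higher and 97 lower genes were called by edgeR alone.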

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

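Every difference in this part was picked out after its value was seen, because the change with PMA went in opposite directions in the 2 lots, and none was tested, since each lot has 1 library per group. ACTB, the beta-actin gene, had a log2 difference of 0.92 in lot 1 and −1.06 in lot 2. Among the gene lists, the median log2 difference in lots 1 and 2 was −0.49 and 0.26 for CDK inhibitors and p53 targets, −0.32 and 0.40 for cholesterol synthesis, and 0.41 and −0.13 for glycolysis. It was 0.13 and −0.54 for mitochondrially encoded mRNAs, 0.25 and −0.24 for replication-dependent histone genes, −0.090 and 0.42 for the unfolded protein and integrated stress responses, and 0.87 and −0.040 for heat shock genes. None of these 7 lists was called in the comparison of all 4 libraries.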

How the results depend on the processing

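Offsets for length and GC content, alone or with the block, and protein-coding genes only were chosen after the results had been seen, and the other settings before. No gene called in the comparison of all 4 libraries was called in the opposite direction in any setting. The counts of 705 higher and 332 lower genes became 2193 and 1712 with DESeq2, 1149 and 636 with limma-voom, 1237 and 869 with length and GC offsets, and 413 and 148 with those and the replicate block. Lower genes were 721 with the stricter filter and 564 with protein-coding genes only, both of which test fewer genes, and 217 against a fold of 1.5. At an adjusted p under 0.01 edgeR called 0 and 0, against 22 in all by limma-voom, 2754 by DESeq2 and 4445 at an unadjusted p under 0.05. Leaving out 1 library, which assumes that the lone library of a group varies like the others, gave 424 to 1830 higher genes (fewest without PMA replicate 2, most without untreated replicate 1) and 79 to 1085 lower genes in the same order. For gene lists, an estimated correlation left 0 of 18 higher and 0 of 8 lower (6 at an unadjusted p under 0.05), and leaving out 1 library gave 13 to 18 and 6 to 10. The pairing by lot gave 591 and 244 genes with the replicate block, of which 517 and 190 were among the 705 and 332, and 16 and 7 lists. The block ended the calls of 8 of 100 called genes among those named by the rule and of 3 lists and changed no other of these calls. With length and GC offsets added to the block, 21 of those genes lost the call. The correlation between lots (0.683) was 0.560 without a filter and 0.818 with the stricter one. Genes that did not pass the test changed sign in some settings. PRKCB (0.10) was at −0.040 with upper-quartile factors, −0.29 with length and GC offsets and −0.31 with these and the block, and ranged from −0.52 to 0.79 when 1 library was left out (−0.39 without untreated replicate 2). Leaving out 1 library gave −2.32 to 0.33 for MT-ND1, −0.28 to 0.011 for GAPDH and −0.93 to 0.75 for ACTB, each with its highest value without untreated replicate 2, and −0.22 (without PMA replicate 2) to 0.97 for MT-CO1. Over all settings and named genes, 2004 values kept their direction and side of the threshold, 189 lost the call, 100 of them at 0.01, and 59 gained one. The cause of these differences was not tested, beyond the number of genes or libraries that a setting leaves. Depth limits genes at or near 0, whose folds are bounds. At the spread of these libraries 22% of simulated 4-fold changes were recovered in genes at 10 CPM or more. The share was 100% at a dispersion of 0.05 with the same 2 libraries per group.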

Other observations

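The 3 gene sets in the first paragraph, the tests of FTH1, the carry-over test, and the comparison of untreated lots for interferon-stimulated genes, including the rule on the spread of its members, were chosen after the results that prompted them had been seen. DCSTAMP and OCSTAMP, membrane proteins needed for the fusion of osteoclasts and macrophages and picked out after their values were seen, rose by 6.23 ± 0.47 on the log2 scale (adjusted p = 0.0161) and at least 3206-fold. Of 15 other osteoclast and cell fusion genes written down, 12 were tested, and ITGB3, CALCR and CA2 were listed at 0 in all 4 libraries. ACP5, TCIRG1, SRC and OSTM1 rose, while the other 8 did not pass, among them CTSK at 1.14 to 3.05 CPM (adjusted p = 0.643) and JDP2 at −1.81 ± 0.36 (adjusted p = 0.0547). The set ranked above the other genes (camera's adjusted p = 0.00287 over the 3 sets, 0.000958 unadjusted). The unadjusted value was 0.00517 without the 2 genes that fixed lists also hold, and 0.0736 with an estimated correlation. After PHGDH and PSAT1 had been seen to fall, 13 of 15 further genes of serine and one-carbon synthesis could be tested and ranked lower (camera's adjusted p = 0.00935 over the 3 sets, 0.00623 unadjusted, and 0.114 with an estimated correlation). In that set SHMT2 fell by 2.04 ± 0.30 (adjusted p = 0.0323) and MTHFD1L by 2.92 ± 0.40 (adjusted p = 0.0293), while the amino acid transporter SLC1A4 rose by 1.96 ± 0.28 (adjusted p = 0.0310) and the other 10 did not pass. TDO2 and KYNU, enzymes of the kynurenine pathway, rose, but the 7 genes tested of 12 others written down did not follow as a set. Their median was −0.49, with 0 past the test (camera's adjusted p = 0.384). KMO was at 3.19 ± 1.27 (adjusted p = 0.192) and the others were below 0. The tested genes included the amino acid transporter SLC7A5 and the tRNA synthetase WARS1, which are not enzymes of the pathway. The hypotheses that PMA may raise cell fusion genes and lower serine synthesis genes as groups thus rest on sets chosen from these data, and neither set passes with an estimated correlation.

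The lower level of cytosolic ribosomal protein genes was weighed against features of the libraries. After the length and GC trend of each library was removed, their median log2 CPM difference was −1.20, against −1.39 before (camera adjusted p = 1.23e-08). This argues against those trends, as fitted, as the whole cause. Lengths were those of the longest annotated transcript of a gene, so a trend with the transcripts present in the cells may remain. Reads moved to pseudogenes would raise the 1065 ribosomal protein pseudogenes, but their summed level was also lower with PMA, by log2 ratios of −1.14 and −1.18 in the 2 lots. Leaving the 20 most abundant and the mitochondrial genes out of the library sizes gave −1.89 for RPL3 and −2.33 for RPS2, against −1.83 and −2.26. TMM factors already limit the weight of such genes, so this test could hardly have come out otherwise and decides nothing. Effects of RNA amount per cell cannot be seen in scaled counts and stay open, as does a response to PMA.

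FTH1 rose 54.5-fold, while FTL, higher in both lots, did not pass the test (adjusted p = 0.0712, and 0.0105 to 0.1996 over 17 alternatives, in 14 of which it did not pass). Reads shared with its pseudogenes or the overlapping BEST1 are argued against, because the sum over these 26 entries rose by at least 54.1-fold in each lot, against at least 52.8-fold for FTH1 alone. The ratio of FTH1 to FTL was 23.2 times as high with PMA as without. FTH1 stood at 3.85% and 3.48% of FTL without PMA and at 67.6% and 103% with it. Whether FTH1 reads were lost in the untreated libraries before the table was made cannot be told apart from a response to PMA, because no value outside these libraries gives the level of FTH1 before treatment, and both may apply.

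Interferon-stimulated genes seemed higher in untreated lot 2 than in untreated lot 1 on a few genes, but the list did not bear this out, with a median log2 difference of −0.83 and 11 of 27 genes higher. The tests meant for that pattern were therefore void (a share of −0.790% for carry-over from the PMA library, −0.24 after the trends were removed, and 0.65 between the PMA libraries). The last value was taken up as a pattern after it was seen, since all 27 genes were higher in PMA lot 2 than in PMA lot 1. It stood at percentile 99.99 of 10000 random lists. Those lists drew genes independently, while the genes of this list may move together (estimated correlation 0.144), so the percentile decides nothing. Length and GC trends, as fitted to the longest transcripts, are argued against as the cause of the pattern, because the median was 0.63 once they were removed. A higher level in lot 2 before PMA stays open, because the members went both ways there, with quartiles of −1.43 and 2.14 around the median of −0.83, and a difference between the lots may be biological, but with 1 library per lot it cannot be told apart from chance or handling.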
